A study of Oryza sativa with 4 samples.

How the data were processed

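RNA was sequenced from roots of 14 day old seedlings of the indica rice cultivar Pusa Basmati 1, in 2 libraries of the wild type and 2 of MADS27OE, 4 libraries in all. Groups were taken from the sample titles and genotypes in the labels. MADS27 is a MADS box transcription factor gene, and the label MADS27OE was read as an overexpression line of it. The labels do not say which promoter or construct was used, how many independent lines there were, or which nitrogen supply the seedlings had.

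The deposited table gives FPKM (mapped fragments scaled to transcript length and to sequencing depth), as the authors made them, for 36843 genes, with 1 value per gene for the wild type and 1 for MADS27OE. How the authors combined the 2 libraries of a genotype is not stated, and no value per library was used here. The submitters' processing notes name cutadapt, HISAT2, Cufflinks 2.2.1 and Cuffdiff, without their roles or settings. The genome build and the annotation are not given in the sources used here. Gene IDs, names and coordinates are those of the deposited table, and 26047 of its genes have no name. A RefSeq gene table was also at hand, but 1 locus ID matched it, so it was not used for names. The starts of the loci were raised by 1, on the assumption that the table counts from 0. A locus can hold up to 10 genes and 9897 genes share one, so a locus is not always the extent of a single gene, and its length includes introns. Overlapping genes and near-identical copies can share reads, and the table does not show how those were divided.

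The values had another form than the planned design assumed. A limma test on 4 libraries and the camera set test had been planned, and neither is possible with 1 value per genotype. The fallback written in advance was used instead. Genes were ranked by the log2 ratio of MADS27OE over the wild type, both with a pseudocount of 1 FPKM, among the 14947 genes with at least 5 FPKM in one genotype, called expressed genes here. The log2 ratio understates differences of genes with low FPKM, while folds given for single genes are ratios of the FPKM themselves and are given only where both are above 0. Counts of genes at least 2-fold or 8-fold higher or lower use the log2 ratio with the pseudocount, so a gene with low FPKM can exceed 2-fold in its FPKM and not be counted. No p-value, error or n belongs to any value, and no difference has a replicate check. Read depth is unknown: among 2295 genes above 0 but below 0.3 FPKM in both, the commonest ratio, with 77 genes, was a log2 ratio of 0.05 to 0.1, and whole reads could not be recovered. The FPKM summed to 691932 in the wild type and 748811 in MADS27OE.

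Gene lists were fixed in advance, 28 in all. Members of 9 lists were given by ID and kept where the name in the table held one of the search words fixed for the list. These words were too narrow for some lists and left out members whose names do belong, such as the RESPONSIVE TO ABA genes, so results with all members by ID are given too. The other 19 lists were built from words in the names, and some searches found few or no genes of their family. A list was described if at least 4 members had a mean FPKM of at least 1. Its median log2 ratio was placed among 10000 random lists of the same size, drawn from the 21724 genes with that mean and matched in 20 bins of mean expression. That percentile is a description of these libraries. A member at very low FPKM in one genotype can meet the mean FPKM of 1 through the other genotype alone. A list was said to stand apart when its median lay outside the middle 95% of the random lists. This rule and the 2-fold limit used for counting genes were set after the form of the data was known.

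The genes to name were set in advance as MADS27 and the 10 genes with the largest log2 ratio in each direction that have a descriptive name. The planned conditions on p-values and on overlap between libraries could not be applied. Because small RNA genes filled much of that ranking, 20 genes per direction without small RNA genes and 5 per direction without a name were added after the values were seen. From each list, members were named by the size of their log2 ratio, since no p-value could order them, and some by their level. A further 13 families were formed from gene names after the leading genes had been seen.

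Settings chosen before the data were examined as comparisons were pseudocounts of 0.1 and 5, no filter beyond a mean FPKM above 0, a mean FPKM of at least 5, rescaling by the median ratio and quantile normalization. Others were added after seeing the data, among them a correction of the log2 ratio for locus length by a locally weighted regression with a span of 0.3. Random lists were also matched on locus length in 2 ways. The first used single-gene loci alone and required 80% of a list's members there, which left 15 of the 19 described lists without a value. The second, added after that result was known, used all loci and matched on mean expression, locus length and whether the locus was shared.

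The ranking and the percentiles were tested on simulated ratios for the 21724 genes, each drawn at random from the ratios of genes within 2-fold. Of 200 genes shifted by a known fold, 200 reached a 2-fold difference after a 4-fold or 8-fold shift, 79 after a 2-fold shift and 17 after a 1.5-fold shift. As every drawn ratio was within 2-fold, the outcome at 4-fold and 8-fold was fixed in advance. Of 20 lists of 12 genes, the number above the middle 95% was 0 without a shift, 12 at 1.25-fold, and 20 at 1.5-fold and at 2-fold. The simulated ratios held no trend with locus length and no likeness within families. They therefore do not show how often a real family would stand apart without a shift. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.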

Results

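The series compared gene expression in roots of 14 day old rice seedlings between the wild type and MADS27OE, as part of work on gene regulation by nitrate. The deposited values are 1 FPKM per gene and genotype from 2 libraries each. There is therefore no spread between replicates, and the differences below describe these libraries. The depth behind the values is unknown.

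MADS27 itself (Os02g0579600, chromosome 2, 22294657 to 22301807, build not given in the sources used here) was higher in MADS27OE, at 51.9 against 17.8 FPKM, a 2.91-fold difference and a log2 ratio of 1.49. This goes with the label of the line. Its log2 ratio was the 569th highest of the 14947 expressed genes. The related genes MADS BOX GENE 23, 25, 57 and 61, which had been fixed as a list with MADS27, lay below 1 FPKM in both genotypes, the highest being MADS BOX GENE 25 in the wild type at 0.800 FPKM.

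Far more genes were higher than lower in MADS27OE. Among the expressed genes, 961 were at least 2-fold higher and 345 at least 2-fold lower, so 73.6% of those beyond 2-fold were higher. At least 8-fold differences were seen for 126 higher and 14 lower genes, and 78.4% of the expressed genes lay within 1.5-fold. Of the higher genes 539 and of the lower genes 194 have no name in the table. With a pseudocount of 5 the counts were 637 higher and 159 lower. The excess of higher genes went with short loci. On single-gene loci of over 600 to 1000 bp 218 were higher and 47 lower, and of over 2500 to 4000 bp 63 and 26. For over 4000 to 8000 bp there were 31 higher and 33 lower, and for over 8000 bp 7 and 11.

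Among the 20 most higher named genes other than small RNA genes, a ranking added after the values were seen, were genes for proline- or glycine-rich, germin-like and peroxidase proteins. Hybrid proline- or glycine-rich protein 4 (Os03g0103200, chromosome 3, 211082 to 211817) was listed at 770.3 FPKM in MADS27OE against 13.1 in the wild type. The root-specific gene RCc2 (Os10g0551800) was at 84.8 against 1.93 FPKM, and hybrid proline- or glycine-rich proteins 3, 6, 7 and 19 were 12.3-fold, 22.002-fold, 31.2-fold and 11.3-fold higher. GERMIN-LIKE PROTEIN 1 (Os08g0460000) was at 319 against 9.96 FPKM, GERMIN-LIKE PROTEIN 8-4 at 208 against 13.7, and GERMIN-LIKE PROTEIN 3-2 at 15.7 against 0.510. Class III peroxidases 95 and 5 were 23.6-fold and 15.9-fold higher.

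The same 20 genes included several transcription factor and signalling genes. An ETHYLENE RESPONSE FACTOR gene (Os09g0522100) was at 74.99 FPKM in MADS27OE against 1.67 in the wild type, and ETHYLENE RESPONSE FACTOR 104 at 20.9 FPKM where the wild type was listed at 0. The DREB1 genes, transcription factors known from cold and dehydration responses, were represented by members 1B (101 against 6.498 FPKM), 1C (18.3 against 0.312) and 1G (11.5 FPKM, listed at 0 in the wild type). ZINC FINGER PROTEIN 15 was 16.1-fold, CALMODULIN-LIKE PROTEIN 31 was 15.7-fold, salt and drought sensitive gene 1 was 15.5-fold and the gene named STRESS_TOLERANCE AND GRAIN_LENGTH was 11.8-fold higher.

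The most lower named genes, again without small RNA genes, were led by an oxalate oxidase. OXALATE OXIDASE 3 (Os03g0693900, chromosome 3, 27788230 to 27788913) was at 38.5 FPKM in the wild type and listed at 0 in MADS27OE, and its neighbour OXALATE OXIDASE 4 was at 0.892 against 26.3 FPKM. FDH2 (Os06g0486900) was at 0.366 against 35.7, jacalin-related lectin 1 at 0.201 against 22.4, and CAFFEIC ACID 3-O-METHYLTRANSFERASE LIKE 2 at 0.0798 against 19.3 FPKM. Terpene synthase 13 and LIPOXYGENASE 11 were listed at 0 in MADS27OE, against 12.9 and 6.45 FPKM in the wild type. Acaulis5 was at 1.23 against 25.9 FPKM, ARGININE DECARBOXYLASE 2, an enzyme of polyamine synthesis, at 4.34 against 35.6, the sugar transporter gene SWEET12 at 0.0797 against 7.34, and BOWMAN-BIRK INHIBITOR 2-2 at 0.3002 against 7.80. Pyruvate orthophosphate dikinase was 7.196-fold, carotenoid cleavage dioxygenase 8a was 7.37-fold, WRKY GENE 50 was 6.84-fold, isocitrate lyase was 14.0-fold and the gene named XYH was 13.0-fold lower.

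Small RNA genes held 8 of the 10 highest and 4 of the 10 lowest places among genes with a name. All 12 were listed at 0 in one genotype, and they carry the names snoZ118, snoZ103, snoZ43, snoZ221_snoR21b, snoZ188, MIR169_2 and U5. Copies of snoZ118 that share one locus of 10 genes on chromosome 2 (780669 to 785676) went both ways, 1 at 222 FPKM in MADS27OE and listed at 0 in the wild type, and 2 at 117 and 55.0 FPKM in the wild type and listed at 0 in MADS27OE. Of the 56 expressed small RNA genes, 35 were at least 2-fold higher and 10 at least 2-fold lower.

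With a pseudocount of 1 the gene with the highest log2 ratio has no name, whereas with 0.1 its value of 8.44 lay below those of small RNA genes listed at 0 in the wild type, such as snoZ118 at 11.12. Os02g0583700 (chromosome 2, 22509550 to 22510620) was listed at 1230.5 FPKM in MADS27OE against 3.44 in the wild type, a 358-fold difference, and lies 208 kb from MADS27. It was 1 of 5 genes at least 8-fold higher within 200 kb there. Os07g0511400 was 82.9-fold and Os08g0556300 was 41.0-fold higher, while Os03g0344400 at 56.9 and Os03g0299700 at 31.1 FPKM were listed at 0 in the wild type. The most lower genes without a name were Os12g0227500 at 1.65 against 34.4 FPKM, Os07g0587300 at 2.17 against 22.4, Os05g0298800 at 0.817 against 12.1, Os10g0361900 at 0.237 against 7.60 and Os08g0136700 at 0.0538 against 6.26.

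**Figure D1:**
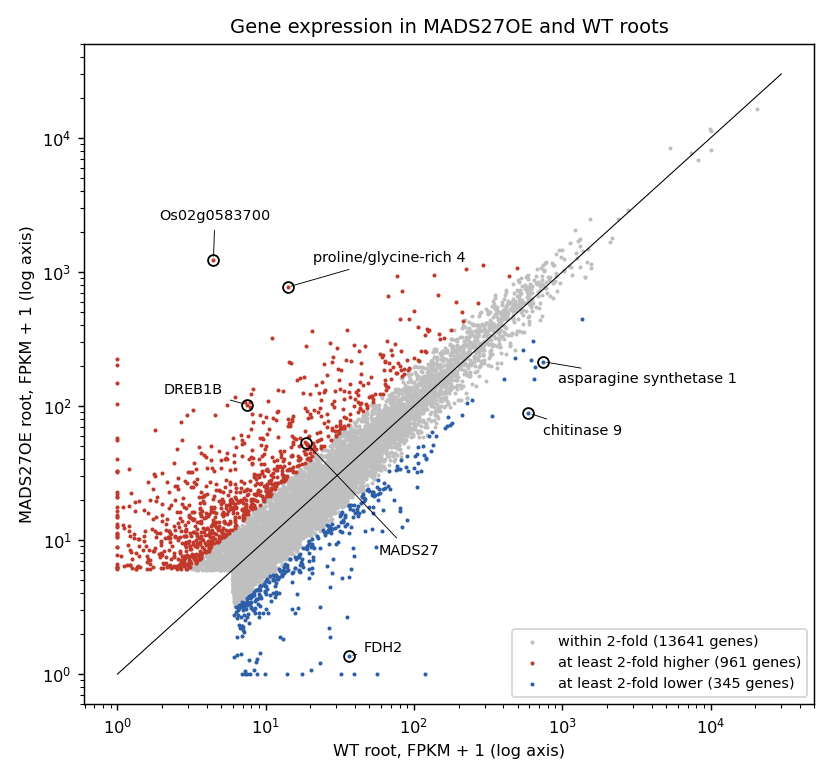
FPKM + 1 of each expressed gene in wild type roots (x axis, log) and MADS27OE roots (y axis, log), with 1 point per gene, the line of equal values, and the genes at least 2-fold higher (961) or lower (345) in colour. MADS27 stands at 17.8 and 51.9 FPKM, and Os02g0583700 lies farthest above the line at 3.44 and 1230.5 FPKM.

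**Figure D2:**
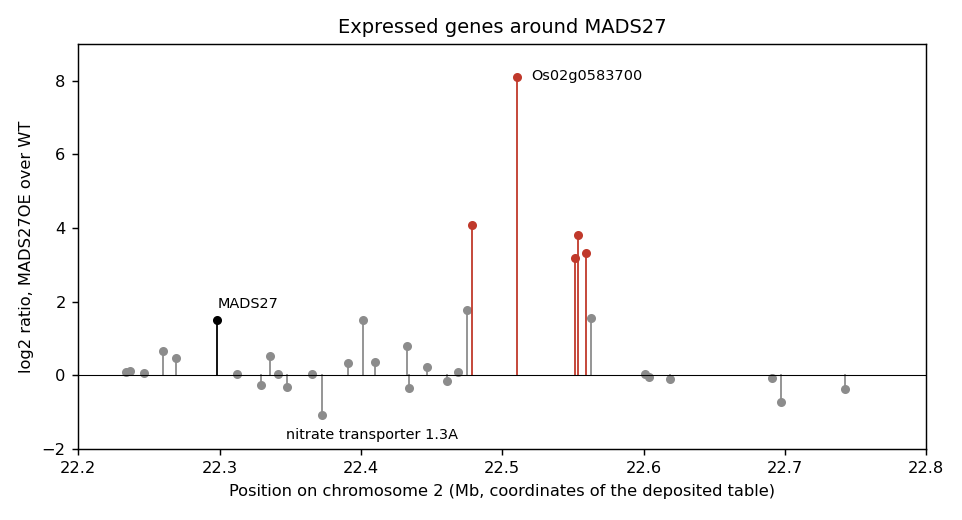
Log2 ratio of MADS27OE over the wild type (y axis) for the 34 expressed genes around MADS27 by position on chromosome 2 (x axis, Mb), with MADS27 in black and genes at least 8-fold higher in red. The 5 red genes lie between 22477790 and 22559609, and nitrate transporter 1.3A lies below 0 at -1.09.

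Members of the nitrate transport list went both ways. An ACTIVATOR FOR NRT2 gene, a high-affinity transporter gene of low FPKM and OsNPF7.2 were higher in MADS27OE. The more abundant nitrate transporter 1.1A was lower, within 2-fold. Of 9 measured members 3 were at least 2-fold higher and 0 lower. An ACTIVATOR FOR NRT2 (Os02g0595900), a partner protein of high-affinity nitrate transporters, was at 41.4 against 8.45 FPKM, a HIGH AFFINITY NITRATE TRANSPORTER (Os01g0704100) at 2.78 against 0.503, and OsNPF7.2 at 5.63 against 1.91. The remaining HIGH AFFINITY NITRATE TRANSPORTER genes were near the floor. Os02g0112100 was listed at 0 in both genotypes. Os02g0112600 was at 0.163 and Os01g0547600 at 0.0714 FPKM in MADS27OE, both listed at 0 in the wild type. The other ACTIVATOR FOR NRT2 (Os04g0480200) was lower at 8.23 against 13.7 FPKM. Nitrate transporter 1.1A was at 43.0 against 58.9 FPKM, nitrate transporter 1.1B at 13.7 against 13.9, and NRT1/PTR family 2.4 at 51.6 against 46.7. The median log2 ratio of the list was -0.01 and its mean 0.33, so they differ in sign, and the median was 0.08 after rescaling by the median ratio. It lay at the 67.54th percentile of random lists, and at the 70.11th, again with a median of -0.01, with all 11 measured members taken by ID whatever their name. That set adds PROTEIN TRANSPORTER 6 (Os04g0597800), at 18.9 against 5.86 FPKM. Nitrate transporter 1.3A (Os02g0580900), which is not in the list, was lower at 10.5 against 23.6 FPKM.

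Of 9 measured nitrogen assimilation genes 3 were at least 2-fold lower in MADS27OE and 0 higher. ASPARAGINE SYNTHETASE 1 (Os03g0291500, chromosome 3, 10116219 to 10124384) was at 213 against 743 FPKM. NADH-DEPENDENT GLUTAMATE SYNTHASE 2 was at 4.43 against 11.8 FPKM and a nitrate reductase gene (Os08g0468100) at 2.80 against 7.02. The nitrate reductase gene OsNIA1 (Os02g0770800) was at 39.2 against 51.1 FPKM. Within 2-fold, GLUTAMINE SYNTHETASE 1 at Os03g0223400 was at 558 against 333 FPKM and at Os02g0735200 at 150.1 against 119.8. GLUTAMATE DEHYDROGENASE 1 was at 63.1 against 71.5, GLUTAMATE DEHYDROGENASE 2 at 26.1 against 27.7, and ASPARAGINE SYNTHETASE (Os06g0265000) at 27.1 against 31.4 FPKM. The list's median was -0.20, at the 7.70th percentile and so inside the middle 95%, and -0.29 at the 1.22nd percentile with all 14 members taken by ID whatever their name. None of the 4 measured ammonium transporters was 2-fold different. AMMONIUM TRANSPORTER-1 at Os02g0620600 was at 44.2 against 55.1 FPKM and at Os04g0509600 at 28.9 against 15.4, and the list median of -0.10 lay at the 45.44th percentile, with a mean of 0.09.

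Of 7 measured members of the phosphate starvation list 4 were at least 2-fold higher in MADS27OE, all of them phosphate transporters. PHOSPHATE TRANSPORTER 2 (Os03g0150800) was at 17.5 against 1.73 FPKM, PHOSPHATE TRANSPORTER 8 at 38.2 against 12.02, PHOSPHATE TRANSPORTER 4 at 16.1 against 5.91 and PHOSPHATE TRANSPORTER 1 at 67.5 against 32.6. By the log2 ratio with a pseudocount of 1 no member was 2-fold lower. The SPX domain genes, known as part of phosphate sensing, differed among themselves: gene 3 was at 1.71 against 0.539 FPKM and gene 2 at 0.761 against 1.72, both beyond 2-fold in FPKM but not in that ratio, and Os06g0603600 at 15.1 against 11.2. The list's median of 1.03 lay at the 99.99th percentile of random lists, and with all 8 measured members by ID it was 0.92 at the 100th. The wider set of 21 phosphate transporter genes taken by name, formed later, had a median of -0.05, with 4 higher and 0 lower.

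**Figure D3:**
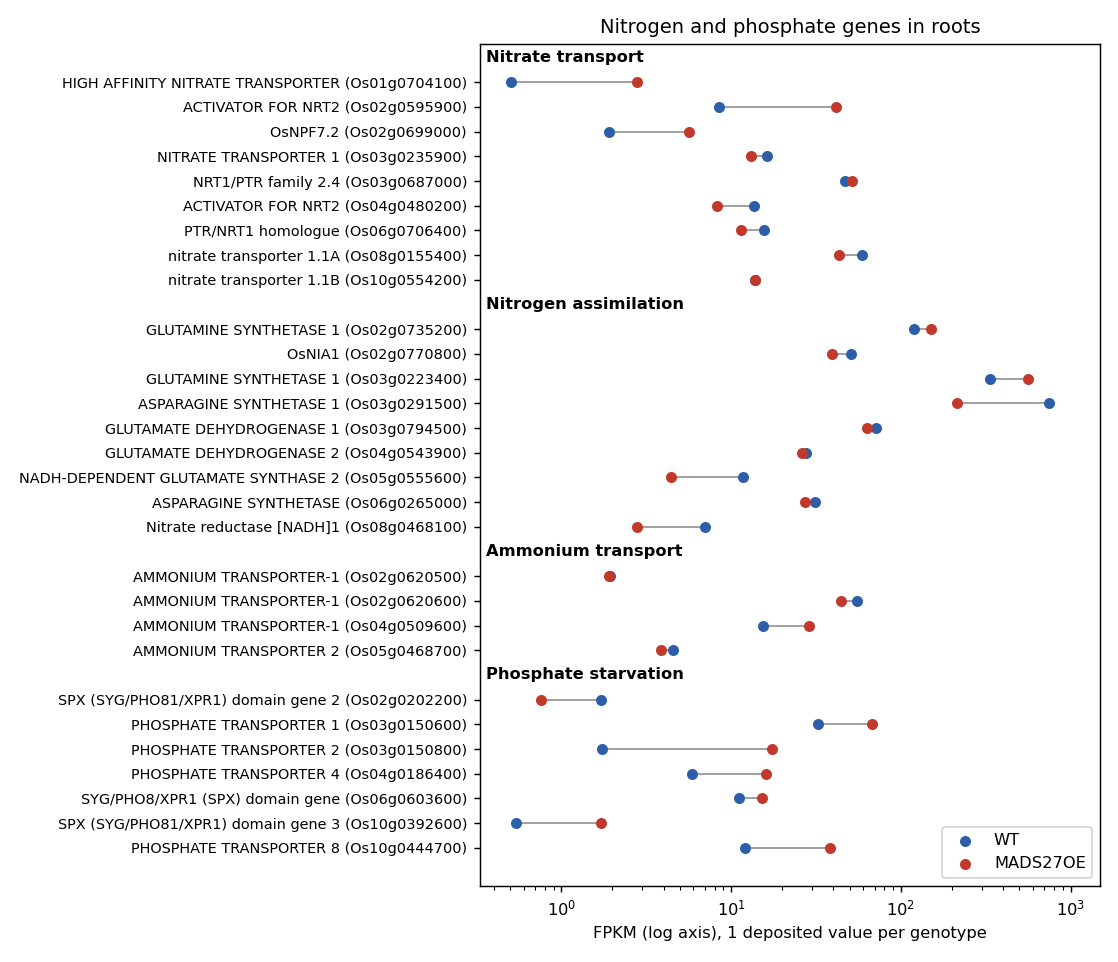
FPKM (x axis, log) of the measured members of the nitrate transport, nitrogen assimilation, ammonium transport and phosphate starvation lists, with 1 blue point for the wild type and 1 red point for MADS27OE per gene. ASPARAGINE SYNTHETASE 1 has the widest gap to the left, from 743 to 213 FPKM, and PHOSPHATE TRANSPORTER 2 the widest to the right, from 1.73 to 17.5 FPKM.

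Of the 28 lists fixed in advance 19 could be described, and 7 stood apart upwards and 2 downwards. With no true difference 0.95 of 19 independent lists would lie outside the middle 95%. That value also takes the genes within a list to vary independently, as in the random lists. Members of a family may not, so the lists that stood apart cannot be weighed against it. Class III peroxidases, enzymes of the cell wall, were the largest such group, with 38 of 88 measured members at least 2-fold higher and 3 lower, a median of 0.58 and the 100th percentile. Class III peroxidase 109 was at 278 against 45.9 FPKM and class III peroxidase 71 at 77.2 against 10.7, whereas class III peroxidase 57 was at 1.88 against 8.001. Some higher members, such as class III peroxidase 102 at 10.8 against 0.206 FPKM, met the mean FPKM only through MADS27OE. Of 29 expansins, which loosen cell walls, 10 were at least 2-fold higher and 0 lower (median 0.22, 99.80th percentile, but 94.16th and inside the middle 95% when matched on locus length), among them ALPHA-EXPANSIN 18 at 7.13 against 0.234 FPKM and ALPHA-EXPANSIN 12 at 13.6 against 1.65. The list meant for xyloglucan endotransglucosylases and cellulose synthases held cellulose synthase and cellulose synthase-like genes alone and had a median of 0.15 (98.88th percentile), but 1 of 31 members was 2-fold higher, CELLULOSE SYNTHASE LIKE C3 at 16.3 against 7.44 FPKM.

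Detoxification and transcription factor families also stood apart upwards. Of 62 glutathione S-transferases 11 were at least 2-fold higher and 3 lower (median 0.25, 99.99th percentile), with TAU GLUTATHIONE S-TRANSFERASE 4 at 513 against 98.5 FPKM and TAU GLUTATHIONE S-TRANSFERASE 43 at 0.878 against 5.39. Of 68 WRKY genes 15 were higher and 7 lower (median 0.10, 99.77th percentile). Their median lay inside the middle 95%, at the 88.07th percentile, when matched on locus length over single-gene loci alone, and outside it, at the 98.39th, over all loci. WRKY GENE 69 was at 66.0 against 6.92 FPKM, WRKY GENE 71 at 90.5 against 17.9, WRKY GENE 76 at 2.95 against 10.8 and WRKY GENE 62 at 2.91 against 9.73. Of 63 NAC genes 10 were higher and 2 lower (median 0.15, 99.98th percentile), including SNAC1 at 143 against 44.1 FPKM.

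Pathogenesis-related genes and chitinases were lower in MADS27OE as a list, with 9 of 28 measured members at least 2-fold lower and 4 higher, a median of -0.28 and the 0.35th percentile. CHITINASE 9 (Os05g0399400, chromosome 5, 19435401 to 19436495) was at 87.7 against 591 FPKM, PATHOGENESIS-RELATED GENE 10A at 4.19 against 31.7, PATHOGENESIS-RELATED GENE 4D at 7.93 against 54.6, and pathogenesis-related protein 8 at 4.69 against 27.01. PATHOGENESIS-RELATED GENE 1A was higher at 22.82 against 7.83 FPKM. Of the terpene synthase list, which by its search words also took in diterpenoid oxidases, 3 of 5 measured members were at least 2-fold lower (median -1.02, 0.02nd percentile). They were terpene synthase 13, ENT-COPALYL DIPHOSPHATE SYNTHASE 4 at 0.113 against 2.25 FPKM and ENT-KAURENE OXIDASE 4 at 3.23 against 7.58. Terpene synthase 13 and ENT-COPALYL DIPHOSPHATE SYNTHASE 4 met the mean FPKM only through the wild type.

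The other described lists lay within the middle 95%. Shoot photosynthesis markers had a median of -0.17 (4.82nd percentile) and were abundant in both genotypes, with CHLOROPHYLL A/B BINDING PROTEIN 2R at 1678 FPKM in MADS27OE against 2114 in the wild type. With all 12 markers taken by ID the median was -0.17 at the 2.19th percentile. Heat shock proteins had a median of -0.14 (17.58th percentile), the 8 measured GH3 genes, the only kind found by the auxin response search, -0.18 (36.76th), AUX1-like and YUCCA-like genes of auxin transport and synthesis -0.19 with a mean of 0.06 (31.80th), abscisic acid and dehydration genes -0.08 (39.77th), gibberellin metabolism -0.07 (56.19th) and phenylpropanoid enzymes -0.03 (53.76th). The last 3 medians turned positive when the values were rescaled by the median ratio, to 0.01, 0.02 and 0.07.

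The abscisic acid and dehydration list rests on 4 measured members, among them the SALT PROTEIN gene at 42.9 against 104 FPKM. With all members taken by ID it had 10, of which 1 was at least 2-fold higher and 3 lower, and its median was -0.22 at the 15.5th percentile. Members named RESPONSIVE TO ABA went both ways, with gene 16D at 24.3 against 1.53 FPKM, 16C at 0.688 against 3.34 and 16B at 1.26 against 6.08. The other 9 lists had fewer than 4 measured members. For diterpenoid phytoalexins and iron deficiency this came from the search words. By ID the diterpenoid list had 4 measured members, 3 of them at least 2-fold lower and 0 higher, and a median of -1.82 at the 0th percentile. MOMILACTONE A SYNTHASE was at 0.186 against 4.85 FPKM, P-450 99A2 at 0.0286 against 3.42 and P-450 99A3 at 2.31 against 4.02, and the remaining member is the ENT-COPALYL DIPHOSPHATE SYNTHASE 4 gene that is also in the terpene synthase list. The 3 lower members met the mean FPKM only through the wild type. By ID the iron list had 7, with 1 higher and 0 lower and a median of 0.14 at the 88.9th percentile. Of the MADS27 list only MADS27 was measured. The name searches found 2 genes each for the NRT1/PTR family, ribosomal proteins and histones, 3 for cytokinin, and 0 for aquaporins and Casparian strip proteins, so these families were largely or wholly missed and these lists say nothing of them.

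The log2 ratio went with locus length. Its median was 1.09 for 68 expressed genes on loci of at most 300 bp, 0.26 for 1161 genes of over 600 to 1000 bp, -0.04 for 3176 genes of over 2500 to 4000 bp, and -0.35 for 599 genes over 8000 bp. These medians include small RNA genes. Without them, the Spearman correlation across 11868 expressed genes on loci of their own was -0.34, and genes are not independent replicates. When random lists were matched on locus length as well, 8 of the 9 lists still stood apart, 6 upwards and 2 downwards, and the expansins did not (94.16th percentile). On single-gene loci alone 4 lists could be placed, and WRKY genes then lay at the 88.07th percentile, inside the middle 95%.

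**Figure D4:**
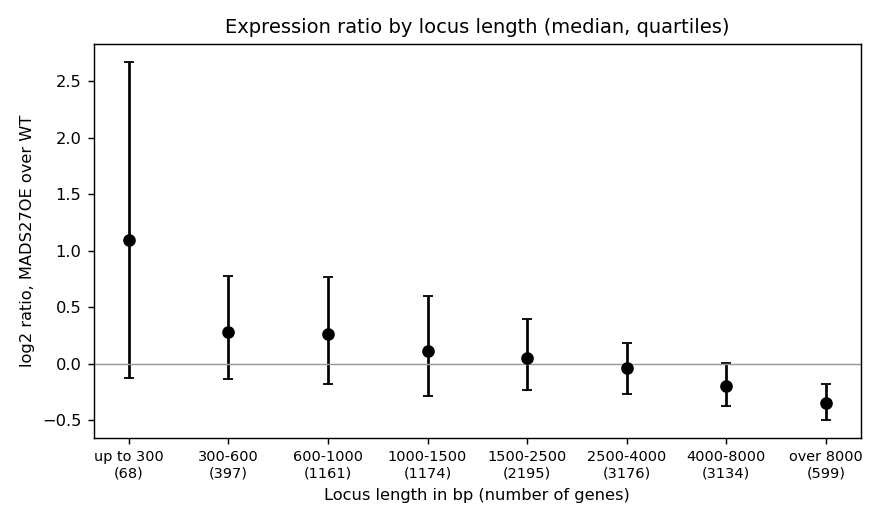
Median log2 ratio of MADS27OE over the wild type (points) with the quartiles (bars) for expressed genes on single-gene loci, small RNA genes included, by locus length in bp (x axis, with the number of genes). The median runs from 1.09 on the shortest loci to -0.35 on the longest.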

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

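The alternatives with locus length, single-gene loci, small RNA genes, a mean FPKM of at least 1 and list members by ID were chosen after the data had been seen. MADS27 had a log2 ratio between 1.32 (pseudocount 5) and 1.76 (corrected for locus length). Of the 62 named genes, 48 had a ratio that moved by over 1.5-fold with a pseudocount of 5 and 34 with 0.1, and none changed direction. The count of genes at least 2-fold higher stayed within 1.5 times of 961 except with a pseudocount of 5, which gave 637, and the lower count stayed within 1.5 times of 345 except there, at 159. A larger pseudocount shrinks the log2 ratio of low genes by construction. Higher genes made up 71.3% to 80% of those beyond 2-fold in every alternative run. On single-gene loci, 752 higher and 239 lower genes became 690 and 266 after correction for locus length, of which 672 and 217 were among the 961 and 345. The number of the 19 described lists outside the middle 95% was 9, between 6 and 11 under the other alternatives, and 2 with length matching on single-gene loci alone. That last value rests on the 4 lists that could be assessed, since the check was void for 15, and 1 of the 4, the WRKY genes, had stood apart before and did not then. With length matching on all loci, added after that outcome was known, it was 8. The median of the basic helix-loop-helix genes, a list formed after the leading genes were seen, reversed from -0.00 to 0.07 with rescaling by the median ratio and to 0.0395 with quantile normalization. No paired analysis was possible because the table holds 1 value per genotype. For the same reason the fits planned with another variance prior, the robust fit, the replicate block, each replicate left out and an estimated inter-gene correlation were not run, and the planned fold minimum was void because the count already used one. Depth is unknown, so genes listed at 0 and folds of low genes have no stated precision.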

Other observations

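The families in the first paragraphs were formed after the leading genes had been seen, and the tests of shoot tissue, handling and locus length as the whole cause for the third pattern were chosen after the results they bear on. The bootstrap intervals below resample genes, since no value per library was used. They hold no spread between libraries. Of 22 measured calmodulin-like genes, encoding calcium sensors, 11 were at least 2-fold higher in MADS27OE and 0 lower (median 0.92, 100th percentile), with CALMODULIN-LIKE PROTEIN 16 at 156 against 15.2 FPKM and CALMODULIN-LIKE PROTEIN 15 at 159.7 against 16.1. Of 10 TIFY genes, a family that includes repressors of jasmonate signalling, 4 were higher and 0 lower (median 0.69, 99.91st percentile), with TIFY GENE 11B at 85.5 against 7.06 FPKM and TIFY GENE 10C at 15.1 against 30.0. All 5 measured DREB1 genes were at least 2-fold higher (median 3.64), DREB1A being at 214 against 26.9 FPKM. Of these, 1E and 1G, listed at 0 in the wild type, and 1C, at 0.312 FPKM there, met the mean FPKM only through MADS27OE. Members 1D and 1F, at most 0.293 FPKM in either genotype, were not measured. The remaining ethylene response factors had a median of 0.03 (85.16th percentile), with 13 of 63 higher and 3 lower, and the median was -0.09 with quantile normalization.

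Of 17 hybrid proline- or glycine-rich proteins 10 were at least 2-fold higher and 1 lower (median 2.66), and the root-specific gene RCc3 was at 944 against 135 FPKM. Of 25 germin-like genes 7 were higher and 4 lower (median 0.37, 99.99th percentile, 95.88th when matched on locus length), and the members named 8-3 (168 against 25.1 FPKM) and 8-10 (4.90 against 15.7) went opposite ways. Of 6 Bowman-Birk protease inhibitors 5 were at least 2-fold lower (median -1.75), among them BOWMAN-BIRK INHIBITOR 3-1 at 218 against 617 FPKM. The oxalate oxidase family had 3 measured members, too few to place. F-box genes had a median of -0.23 over 258 members with 4 higher and 1 lower (0th percentile, also when matched on locus length). As 253 of them were within 2-fold, a large family can lie outside the middle 95% through a slight common shift. Metallothioneins had a median of 0.11 over 12 (44.88th percentile, 0 with quantile normalization), and water channels named intrinsic proteins 0.04 over 27 (64.66th percentile, -0.18 with quantile normalization). Phosphate transporters taken by name, 21 genes of several families, had a median of -0.05 and a mean of 0.31, and the median was 0.05 after rescaling by the median ratio. The 103 basic helix-loop-helix genes had a median of -0.00 and a mean of 0.17 (98.41st percentile).

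The 5 unnamed genes at least 8-fold higher on chromosome 2 (Os02g0582900, Os02g0583700, Os02g0584700, Os02g0584800 and Os02g0585100) lie from 22477790 to 22559609, and no other 200 kb window held as many. Chance placement is argued against by 1000 shuffles of the ratios over the expressed genes, of which a share of 0.001, the smallest they can give, counted as reaching 5. The pattern had first been noticed in these same values, and the shuffles took no account of locus length. Extra copies of the whole interval around MADS27, from 22233461 to 22743361, are argued against by its other 28 expressed genes. Their median log2 ratio was 0.06 (95% bootstrap interval -0.06 to 0.23). The span of the 5 genes holds no other expressed gene, so this median cannot decide on extra copies of that span alone. The expressed genes next to the span were also higher, Os02g0582800 at 29.7 against 7.97 FPKM and Os02g0585200 at 8.09 against 2.08. Neighbouring related genes that respond together, reads shared between such copies, a change at this site brought in with the transgene, and the genotype itself stay open and untested, since no sequence or value per library was analysed here.

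The higher ratios of short genes were not made by a few strongly different ones, since the Spearman correlation of locus length with the log2 ratio was -0.31 (95% bootstrap interval -0.32 to -0.29) across the 10906 genes within 2-fold. The correlation was below 0 in 14 of 14 name families with at least 40 genes, that is in 100%, at -0.38 to -0.01. In 13 of the 14 it was closer to 0 than the -0.34 over expressed genes without small RNA genes. A length-dependent difference between the libraries or in the FPKM estimates may therefore account for part of the trend, and a part tied to gene families or function stays open. Whether it arose in fragment size, RNA quality, the effective length used for FPKM or the genotype cannot be settled with 1 value per genotype.

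The 37 measured DREB1, calmodulin-like and TIFY genes had a median log2 ratio of 1.08, with 20 at least 2-fold higher and 0 lower. At the lengths of the 34 members on single-gene loci the trend with locus length gives a median of 0.14 (95% bootstrap interval 0.10 to 0.16). This lies below their own median of 1.04 (0.37 to 2.51). The families were picked for their high members, so their own median is high by selection. The comparison therefore cannot exclude the trend as the whole cause. The length-corrected median of the 34 members was 1.03 (95% bootstrap interval 0.31 to 2.39). By a bound set before the result was seen, it had to lie above 0.58 by more than its interval. It did not, so whether any remainder beyond the trend exceeds that bound stays open. More shoot tissue in the MADS27OE samples is argued against by the shoot marker median of -0.17 (95% bootstrap interval -0.22 to -0.02). That interval is over marker genes, not libraries. The median does not argue against a smaller share of shoot tissue in the MADS27OE samples, which was not tested and stays open. Handling of the roots at harvest cannot be told apart from the genotype with 1 value per genotype, whatever the lists chosen for it show. Those lists differed, with WRKY genes at the 99.77th percentile and heat shock proteins at the 17.58th. Matched on locus length, WRKY genes lay at the 98.39th percentile over all loci but at the 88.07th over single-gene loci alone. A response to MADS27 may therefore be only 1 of the open explanations.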
